A study of Mus musculus with 6 samples.

How the data were processed

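Total RNA from heart ventricles was labelled with Cy3 and hybridised to one-colour Agilent arrays, 3 for Tead1 icKO and 3 for control mice, per the labels' protocols. The deposited scanner files hold spot intensity in linear units from Agilent Feature Extraction 11.0.1.1 on array design 028005, which uses mouse genome build mm9, per the file headers. The submitters' processing notes name Feature Extraction 9.1 instead. The processed signal had been background-subtracted within each array before deposit, per the file headers, with no scaling between arrays. The authors' deposited value table holds intensity on a linear scale. Its columns correlated with each array's own log2 scanner values at 0.9995 or more, with column medians between 18.37 and 18.47, and the sorted columns, less their lowest 100 values, lay within 1.38% of their mean, so they may have been quantile-normalized. The method behind it is not given in the sources used here. The values are uncentred intensities of single arrays, so no direction had to be settled.

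All 6 arrays lay on 1 slide and were scanned together, so the planned slide block was not run. Controls lay in slide columns 1, 1 and 2 and icKO arrays in columns 2, 3 and 3. An effect of position across the slide can therefore hardly be told apart from the group difference. Each array held 62976 spots. Their 75th percentile signal was 189, 233 and 215 in controls and 312, 348 and 292 in icKO. Between 47.7% and 50.9% of probes lay well above background, and there were 0 saturated spots. The number of arrays limits the precision.

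Processed signals were log2-transformed and each array's 75th percentile over non-control probes was subtracted. Spots with an outlier flag were left out, and spots of a probe were averaged. A probe was kept where it was well above background on all 3 arrays of at least 1 group, which left 26152 of 55681 probes. Probes were named through their RefSeq accession, without versions, in a RefSeq gene table of assembly GRCm38.p6, used for names only since the design uses another build. This named 26582 probes of 20145 genes. The 29099 unnamed probes include 16194 that cover genomic intervals, and each was tested by itself. A gene stands for its brightest kept probe by mean over all 6 arrays. For 35 genes, kept probes passed in opposite directions, among them Itgam and Ldb3. Kept probes of Cdkn1a, Nfatc2, Nrf1, Ppargc1a and Ucp3 also differed in sign.

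Groups were compared with limma 3.58.1 (lmFit and eBayes, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment over all 22278 features and a threshold of 0.05. Every adjusted p of a gene comes from that fit. A probe that was not well above background on any array of a group has only a bound there: the bright group's mean was set against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Such differences are given as "at least N-fold". Where some arrays of a group measured a probe, the fitted difference is given with their number. The 32 gene lists, fixed before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists, and with fry. Differences of lists are means over members relative to all features.

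The rule for named genes, also fixed before the data were examined, has 4 parts. It takes Tead1 to Tead4, and the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups do not overlap, leaving out clone and predicted gene names. It adds 19 genes fixed whatever their result (Atp2a2, Pln, Ryr2, Casq2, Slc8a1, Cacna1c, Ppp1r1a, Nppa, Nppb, Myh6, Myh7, Acta1, Ppargc1a, Esrra, Col1a1, Postn, Ccn1, Ccn2 and Ankrd1). Last, it takes up to 2 members that rose and 2 that fell with the smallest p from each list. Col15a1, Cox6a1, Cox8a, Bcl2 and Bcl2l1, and the genes named in the closing section outside this rule, were chosen after their values were seen. Some genes that the rule takes are not reported here.

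The steps were tested on simulated data with 200 of 22278 genes changed, 3 arrays against 3. The fit recovered 5.97% of genes changed 1.5-fold, 37.3% of those changed 2-fold and 86.4% of those changed 4-fold, all in the right direction. Of 93 calls, 7 were false (7.53%). In the data 9974 features were called (44.8%), a far larger share than was changed in the simulation. Recovery depends on that share under Benjamini-Hochberg adjustment, so these rates may not hold for the real comparison. Other settings chosen before the data were examined were normexp background correction, quantile and median scaling, the authors' value table, 2 other filters on dim probes, outlier spots kept, the mean of a gene's probes, trend and robust eBayes, array weights, a replicate block, leaving out each array, a minimum fold change, an estimated inter-gene correlation, fry, and lists without shared members. The files used here hold no mean spot signal, so normexp (offset 50) was run on the median spot signal, chosen after seeing the data. Scaling to 6 E1A spike-in probes and the row of the array on the slide as a block were also added after seeing the data, as were the TEAD and Hippo list without Vgll2, the bounds without each array and the MCAT list under each setting. Figures were drawn with matplotlib 3.10.9.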

Results

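Messenger RNA levels were measured in heart ventricles of male C57bl/6j mice aged 11 to 12 weeks, on 6 one-colour Agilent arrays. The 3 Tead1 icKO mice carried floxed Tead1 alleles and the Myh6-CreER transgene, a tamoxifen-activated Cre recombinase made in cardiomyocytes. The 3 control mice carried floxed Tead1, and both groups received tamoxifen. The labels name no Cre in the controls, so loss of Tead1 and presence of Cre cannot be told apart in this design. Tead1 encodes a DNA-binding factor that works with the coactivators YAP and TAZ. Between 47.7% and 50.9% of probes lay well above background on each array, and no spot was saturated. The number of arrays, 3 per group, limits the precision of every value.

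The Tead1 probe used for the gene was lower in icKO ventricles by a log2 difference of -0.40 ± 0.11 (SE, n = 3 and 3; limma, Benjamini-Hochberg adjusted p = 0.030). Its mean fell from 3.92 ± 0.12 to 3.52 ± 0.12 (SD) on the log2 scale. The other Tead1 probes gave -0.43 and -0.19. Where these probes lie relative to the deleted part of the gene is not known here, so they do not check the labels. The call was lost with median scaling (-0.24, adjusted p = 0.186), and the sign turned with scaling to spike-in probes (0.06, adjusted p = 0.753). It was also lost without control replicate 1 (-0.35), control replicate 3 (-0.38), icKO replicate 2 (-0.36) or icKO replicate 3 (-0.37). The same held with no filter on dim probes (adjusted p = 0.122). As a block, replicate number gave an adjusted p of 0.0509 and slide row 0.0631. Among the related factors, Tead3 rose by 0.83 ± 0.13 (adjusted p = 0.00339), a call lost with normexp background correction (0.08, adjusted p = 0.525). Tead2 differed by 0.12 ± 0.15 (adjusted p = 0.568), or 0.58 with spike-in scaling (adjusted p = 0.0488). Tead4, not well above background in controls, was at least 2.21-fold brighter in icKO, or 1.27-fold without icKO replicate 3, with an adjusted p of 0.0958. That probe stood at -0.85 on icKO replicate 3 and at -3.17 and -3.34 on the other icKO arrays, and without replicate 3 its fitted difference of 1.54 became 0.74 (adjusted p = 0.0206). It was also called higher with spike-in scaling (adjusted p = 0.0319).

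Of 22278 features tested, 9974 differed, 3573 higher and 6401 lower in icKO (limma, Benjamini-Hochberg). Named genes were 12974 of the features and 6256 of those that differed, 2636 higher and 3620 lower. Of the genes listed for extracellular matrix, macrophages and inflammation, 36 of 37, 15 of 18 and 18 of 28 rose. Of those listed for respiratory complexes, the citric acid cycle and fatty acid oxidation, 77 of 79, 25 of 25 and 26 of 35 fell, or 32, 12 and 15 with spike-in scaling. With an estimated correlation the camera adjusted p of these 6 lists was 0.308 to 0.51. Correlations between arrays were 0.989 to 0.992 within controls, 0.987 to 0.992 within icKO and 0.947 to 0.958 between groups. The first principal component held 74.8% of the variance and separated the groups. All 3 icKO arrays lay on one side of all 3 controls for 59.3% of features, where chance gives 10%. The balance of directions depended on scaling: 35.8% of calls were higher with the 75th percentile, 54.6% with median scaling and 82.5% with spike-in scaling. The median feature lay at -0.14, and these 2 other scalings added 0.16 and 0.46 to every log2 difference.

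The largest rises among named genes included secreted matrix proteins and a steroidogenic gene. Star, which carries cholesterol into mitochondria, rose by 6.61 ± 0.18 (SE) on the log2 scale (adjusted p = 4.04e-05). Comp and Ltbp2, both matrix proteins, rose by 6.05 ± 0.26 and 5.82 ± 0.32. Serpina3n, a protease inhibitor, rose by 5.46 ± 0.38. Sprr1a was at least 26.7-fold, Col8a2 at least 20.1-fold, Ecrg4 at least 17.5-fold and Chil1 at least 11.9-fold brighter in icKO, since none was well above background in controls. Without icKO replicate 2 the Sprr1a bound was 14.3-fold. Vgll2, a TEAD cofactor, differed by 10.31 ± 0.59 (adjusted p = 0.000184), a size that is uncertain because 1 of 3 control arrays was above background. Cdo1 rose by 5.45 ± 0.39, again with 1 of 3 controls above background. Esr1, the estrogen receptor gene, gave 8.59 ± 1.08 (adjusted p = 0.00176) through 1 of its 3 probes, which was above background on 1 of 3 controls, so its size is uncertain too. The remaining Esr1 probes differed by 0.10 and 0.18 and were above background on at most 1 array.

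Among the largest falls were Igsf1 (-5.70 ± 0.20, SE), the phospholipase Pla2g5 (-5.69 ± 0.17) and Scn4b, a sodium channel beta subunit (-5.53 ± 0.19). Colq, which anchors acetylcholinesterase, fell by 5.42 ± 0.18 and the amino acid transporter Slc36a2 by 5.26 ± 0.16. Scgb1c1, Prr33 and Mybpc2 fell by 5.14 ± 0.14, 4.99 ± 0.33 and 4.81 ± 0.16, with Prr33 above background on 2 of 3 icKO arrays. Meig1 was at least 26.9-fold, Pdzd3 at least 24.0-fold, Tmprss13 at least 10.3-fold and Prss55 at least 4.87-fold dimmer in icKO, where none was well above background. The adjusted p of these falls lay between 2.72e-05 for Meig1 and 0.000476 for Tmprss13 (limma).

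Collagens and other extracellular matrix genes rose together. Of 37 measured members of that list, 36 rose and none fell, and Col15a1 differed by 0.16 (adjusted p = 0.787). Postn, a matricellular protein, rose by 4.49 ± 0.27 (SE), Thbs4 by 4.60 ± 0.20 and Col1a1 by 1.93 ± 0.25. Relative to all genes the list lay 2.54 higher in icKO (camera adjusted p = 3.57e-20, adjusted p = 0.35 with an estimated correlation). Of 18 macrophage markers, 15 rose and none fell, 18 and none with spike-in scaling, among them Lgals3 by 3.45 ± 0.25 and Ctss by 2.05 ± 0.24 (list 1.49 higher, camera adjusted p = 2.18e-08, adjusted p = 0.397 with an estimated correlation). Of 28 inflammation genes, 18 rose, 21 with spike-in scaling, including Tlr2 by 2.30 ± 0.14 and Vcam1 by 1.26 ± 0.09 (list 1.31 higher, camera adjusted p = 2.04e-07, adjusted p = 0.308 with an estimated correlation). Cxcl9 was the 1 member that fell (-1.72), a call lost without control replicate 1 (-1.68), control replicate 3 (-1.61) or icKO replicate 3 (-1.81) and with no filter on dim probes (adjusted p = 0.0747). Of 19 fibroblast markers, 12 rose and 1 fell, 17 and 1 with spike-in scaling, with Mfap5 at 2.61 ± 0.29 and Scara5 at -1.97 ± 0.29 (list 1.03 higher, camera adjusted p = 2.19e-05, adjusted p = 0.444 with an estimated correlation). Col1a1, Col3a1 and Postn belong to both the matrix and the fibroblast lists.

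**Figure D1:**
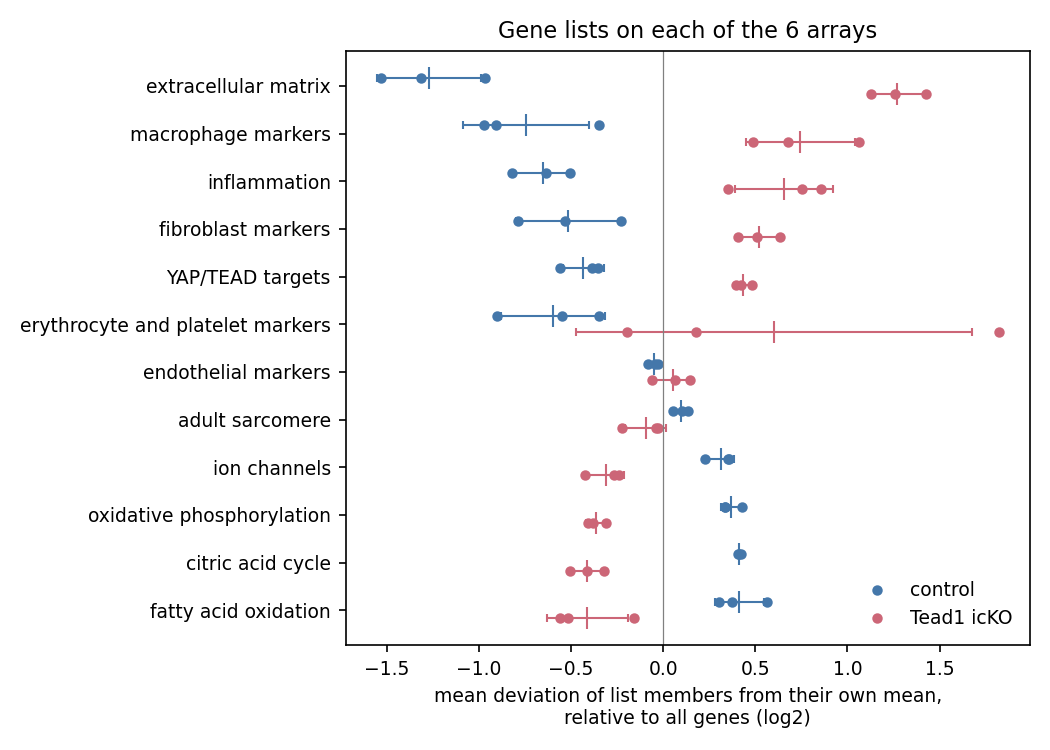
Mean deviation of the members of 12 gene lists from each member's own mean, relative to all genes (log2, x axis), on each of the 3 control and 3 Tead1 icKO arrays. Points are arrays, ticks are group means and bars are SD; the matrix list lay between -1.53 and -0.97 in controls and between 1.13 and 1.43 in icKO, while 1 icKO array stood at 1.82 for erythrocyte and platelet markers.

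Genes of mitochondrial energy metabolism fell. Of 79 nuclear-encoded subunits of the respiratory complexes, 77 fell and none rose, and the list lay -0.73 relative to all genes (camera adjusted p = 2.15e-18, adjusted p = 0.393 with an estimated correlation). Cox7a1, a heart and muscle subunit of complex IV, fell by 1.43 ± 0.10 (SE) and Uqcrc1 of complex III by 1.34 ± 0.09. The 2 members that did not pass were Cox6a1 and Cox8a, named after their values were seen. All 25 pyruvate dehydrogenase and citric acid cycle genes fell, including Suclg1 by 1.40 ± 0.10 and Idh3b by 1.28 ± 0.09 (list -0.82, camera adjusted p = 1.96e-09, adjusted p = 0.357 with an estimated correlation). Of 35 fatty acid oxidation genes, 26 fell and 2 rose. Acaa2 and Hadh of mitochondrial beta-oxidation fell by 2.56 ± 0.13 and 2.10 ± 0.11, and Ucp2 rose by 1.42 ± 0.23 (list -0.82, camera adjusted p = 5.66e-07, adjusted p = 0.51 with an estimated correlation). The other gene that rose, Ucp3 (1.02 ± 0.24), gave -0.61 with another probe, and its call was lost with the mean of its probes (0.20) and with no filter on dim probes (adjusted p = 0.0592). With spike-in scaling the counts that fell were 32 of the 79, 12 of the 25 and 15 of the 35, and 2, 0 and 3 rose.

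Regulators of mitochondrial biogenesis were mixed, with 12 of 22 lower and 2 higher, or 3 lower and 5 higher with spike-in scaling (camera adjusted p = 0.164). Rxrg fell by 2.22 ± 0.11 (SE) and Polrmt, the mitochondrial RNA polymerase, by 0.92 ± 0.11, a call lost with spike-in scaling (-0.46, adjusted p = 0.0744). Klf15 rose by 0.86 ± 0.14. Esrra fell by 0.56 ± 0.12 (adjusted p = 0.0124), a call lost with median scaling (adjusted p = 0.0737), no filter on dim probes (adjusted p = 0.0604) and spike-in scaling (adjusted p = 0.708). Ppargc1a differed by -0.46 ± 0.22 (adjusted p = 0.136, limma) and without control replicate 2 by -0.69 (adjusted p = 0.0275). Its dimmer probe gave 0.12, and the mean of its probes -0.17 (adjusted p = 0.541).

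Calcium handling genes included both falls and differences that did not pass. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 0.96 ± 0.10 (SE; adjusted p = 0.000901), and its inhibitor Pln by 0.92 ± 0.10 (adjusted p = 0.00113), though with spike-in scaling the Pln call was lost (-0.45, adjusted p = 0.0887). Hrc fell by 1.23 ± 0.08, Ppp1r3a by 1.47 ± 0.13, and Jsrp1 rose by 3.35 ± 0.18. The ryanodine receptor Ryr2 differed by 0.05 ± 0.10, the exchanger Slc8a1 by 0.20 ± 0.12 and the channel subunit Cacna1c by -0.04 ± 0.11 (adjusted p = 0.72, 0.218 and 0.758), and Slc8a1 was called higher with spike-in scaling (0.66, adjusted p = 0.0146). Casq2 fell by 0.42 ± 0.12 (adjusted p = 0.0301), a call lost with no filter on dim probes, the authors' value table, and quantile, median and spike-in scaling, the last turning its sign (0.04). It was also lost without any of the 3 controls (-0.42, -0.47 and -0.37) and without icKO replicate 2 (-0.33) or 3 (-0.47). Ppp1r1a was not well above background on any array. In all, 10 of 29 members fell and 2 rose, against 4 and 6 with spike-in scaling (camera adjusted p = 0.126).

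The balance of adult sarcomere genes depended on scaling. Of 29 measured, 18 fell and 4 rose, against 7 and 7 with quantile normalization and 4 and 7 with spike-in scaling (camera adjusted p = 0.0943). The list was called lower with trend and robust eBayes (adjusted p = 0.0377), with no filter on dim probes (adjusted p = 0.0314) and by fry (adjusted p = 0.0109). Tnni3, cardiac troponin I, fell by 1.03 ± 0.09 (SE) and Mylk3 by 1.29 ± 0.10, while Xirp1 rose by 1.85 ± 0.21 and Flnc by 0.75 ± 0.15. Myh6, the adult myosin heavy chain, fell by 0.69 ± 0.14 (adjusted p = 0.00852), but gave -0.02 with quantile normalization and with the authors' value table, and -0.23 with spike-in scaling (adjusted p = 0.228). Of 28 ion channel and gap junction genes, 16 fell and 5 rose, against 9 and 6 with spike-in scaling (camera adjusted p = 0.077), and the list was called lower without control replicate 1 (adjusted p = 0.0363), without icKO replicate 3 (adjusted p = 0.0447), and with median, quantile and spike-in scaling, the authors' value table and no filter on dim probes (adjusted p = 0.0209, 0.0285, 0.00133, 0.0287 and 0.0169). Kcnip2, a potassium channel subunit, fell by 4.34 ± 0.26, with 2 of 3 icKO arrays above background, and Gjc1 rose by 0.99 ± 0.16.

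Fetal and stress-associated cardiac genes divided. Of 22 measured, 12 rose and 5 fell, 14 and 4 with spike-in scaling (list 1.19 higher than all genes, camera adjusted p = 0.000732, adjusted p = 0.416 with an estimated correlation). The call was lost when members shared with other lists were removed (0.37 higher, adjusted p = 0.359). With spike-in scaling it was lost too (adjusted p = 0.0751), though the list still lay 1.19 higher. Rcan1, a calcineurin regulator, rose by 2.33 ± 0.13 (SE). Skeletal alpha-actin Acta1 fell by 2.69 ± 0.32 (adjusted p = 0.00143) and Tnnt1 by 2.29 ± 0.09. The natriuretic peptide gene Nppb was lower by a log2 difference of -1.79 ± 0.54 (adjusted p = 0.0354). That call was lost without control replicate 1 (-1.35), control replicate 3 (-1.58) or any icKO array (-1.73, -1.76 and -1.89), and with median scaling (adjusted p = 0.0510), slide row as a block (adjusted p = 0.0546) and no filter on dim probes (adjusted p = 0.106). Nppa differed by 0.46 ± 0.39 (adjusted p = 0.371) and Myh7 by 0.64 ± 0.30 (adjusted p = 0.126). Nppa was called higher with spike-in scaling (0.92, adjusted p = 0.0394). Myh7 was called higher without control replicate 2 (0.90, adjusted p = 0.0484), with normexp (0.73, adjusted p = 0.0470) and with spike-in scaling (adjusted p = 0.0386).

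**Figure D2:**
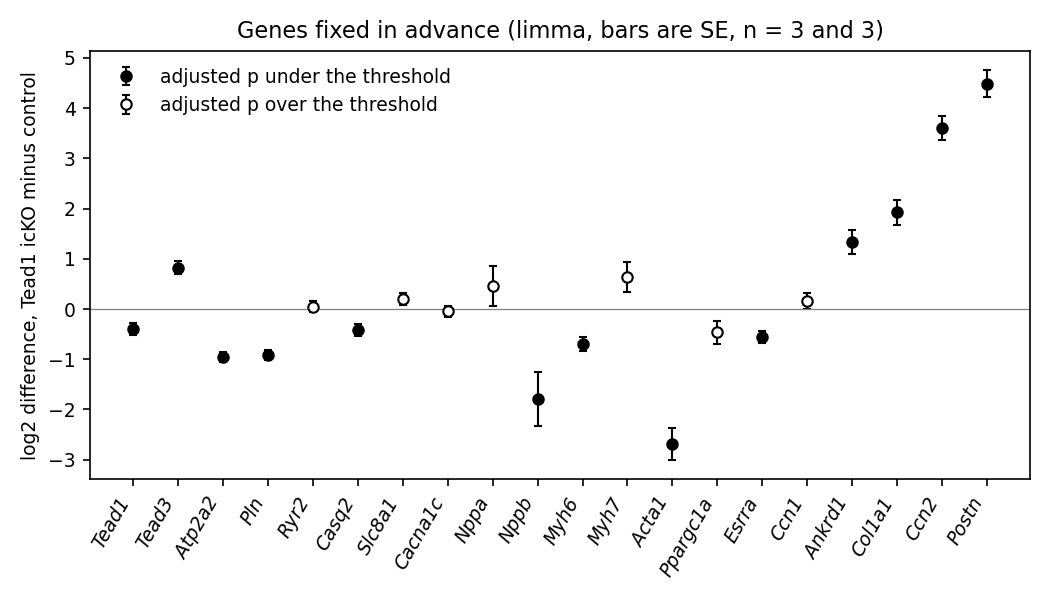
Log2 difference between Tead1 icKO and control (y axis) for 20 genes, with SE bars from limma (n = 3 and 3). Filled points passed the adjusted p threshold and open points did not. Acta1 lay at -2.69 and Postn at 4.49. Of the genes with filled points, Tead1 and Casq2 turned sign with spike-in scaling.

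Genes used as readouts of YAP and TEAD activity in cultured cells were mostly higher or did not pass. Of 28, 15 rose and 1 fell, 21 and 1 with spike-in scaling (list 0.87 higher, camera adjusted p = 3.22e-05, adjusted p = 0.308 with an estimated correlation). Ccn2, a secreted matricellular protein, rose by 3.61 ± 0.24 (SE), Ankrd1 by 1.34 ± 0.24 and Nt5e by 1.91 ± 0.19. Dock5 was the 1 that fell (adjusted p = 0.00168), and Ccn1 differed by 0.15 ± 0.16 (adjusted p = 0.465), or 0.61 with spike-in scaling (adjusted p = 0.0178). Ccn2 is also a member of the matrix and fetal lists. Of 22 TEAD and Hippo pathway genes, 12 rose and 2 fell, 17 and 1 with spike-in scaling (list 0.99 higher, camera adjusted p = 0.000261, adjusted p = 0.308 with an estimated correlation). Without Vgll2, left out after the data were seen, that list lay 0.54 higher (camera adjusted p = 0.00095, adjusted p = 0.308 with an estimated correlation). Vgll3 rose by at least 1.68-fold, a call lost with normexp (0.17, adjusted p = 0.193), and Amot fell by 1.26 ± 0.16. Of 26 apoptosis regulators, 12 rose and 3 fell, against 19 and 0 with spike-in scaling (list 0.59 higher, camera adjusted p = 0.000215, adjusted p = 0.308 with an estimated correlation). The rises included Bid, which promotes cell death, by 1.68 ± 0.12, and Pmaip1 by at least 2.78-fold. Bcl2 and Bcl2l1, which oppose cell death, also rose (1.45 and 0.85), and Cycs fell by 0.90 ± 0.12, a call lost with spike-in scaling (-0.44, adjusted p = 0.0908).

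Markers of other cell types gave rises and falls. Of 20 endothelial markers, 3 rose and 5 fell, against 4 and 2 with median scaling and 6 and 1 with spike-in scaling (camera adjusted p = 0.871), with Vwf at 2.14 ± 0.30 (SE) and Aqp1 at -1.42 ± 0.16. Of 16 smooth muscle and pericyte markers, 2 rose and 6 fell, against 3 and 3 with spike-in scaling (camera adjusted p = 0.395). Of 9 epicardial markers, 3 rose, 5 with spike-in scaling, including Krt18 by 1.59 ± 0.32 (list 1.05 higher, camera adjusted p = 0.0194, adjusted p = 0.35 with an estimated correlation). The call was lost with median scaling (adjusted p = 0.0525) and spike-in scaling (adjusted p = 0.222), though the list still lay 1.05 higher with each. The arrays overlapped, with epicardial markers at -0.13, 1.06 and 0.65 in icKO and -0.47, 0.04 and -1.15 in controls, and those of the endothelial and of the smooth muscle and pericyte lists overlapped too. Of 10 erythrocyte and platelet markers, 4 rose, 7 with median or spike-in scaling (camera adjusted p = 0.0175, adjusted p = 0.58 with an estimated correlation). The call was lost with spike-in scaling (adjusted p = 0.135), though the list still lay 1.20 higher. That list stood at 1.82 on icKO replicate 1 and at -0.20 and 0.18 on the other icKO arrays, and its excess of 1.20 became 0.58 without replicate 1. Neutrophil markers, 4 of 8 higher and 1 lower, 4 and 0 with spike-in scaling (camera adjusted p = 0.169), also stood highest on that array, at 1.46 against 0.32 and 0.33, and were called higher with no filter on dim probes (adjusted p = 0.00183). Lymphocyte markers (2 of 9 higher, 3 lower), adipocyte markers (2 of 5 higher) and neural markers (2 of 10 higher, 3 lower) gave camera adjusted p of 0.703, 0.146 and 0.774. With spike-in scaling these counts were 3 and 0, 3 and 0, and 2 and 1, and with median scaling no lymphocyte marker fell. Of 9 atrial and conduction markers, 4 rose and 2 fell, 5 and 2 with spike-in scaling (camera adjusted p = 0.2).

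With its preset correlation of 0.01, camera called 13 of 32 lists, 10 higher and 3 lower, and the 9 other ways of splitting the 6 arrays into 3 and 3 called 7 to 15 lists each. Those splits mix arrays of both groups and so keep part of the group difference. Their counts therefore do not show how many lists camera calls where no difference exists. With an estimated correlation camera called 0 lists, with 4 at an unadjusted p under the threshold (inflammation, YAP and TEAD targets, apoptosis, and TEAD and Hippo genes), and fry, which tests a list without comparing it with other genes, called 23. These were the 13 less erythrocyte and platelet markers (fry adjusted p = 0.221), and the lists of sarcomere, calcium handling, ion channel, glycolysis, heat shock and p53 genes, mitochondrial regulators, cardiac transcription factors, and adipocyte, atrial, and smooth muscle and pericyte markers. Calls of fry depend on the scaling, and it was run with the main scaling only. For lists that fry but not camera called lower, the median difference with spike-in scaling was -0.12 for ion channels. It was positive for the others, from 0.03 for mitochondrial regulators to 0.35 for glycolysis. It stayed negative for respiratory subunits (-0.39), the citric acid cycle (-0.46) and fatty acid oxidation (-0.54). An exact two-sided permutation of the array labels cannot give a p under 0.1 with 3 against 3. Adjusted over the list alone, the members that rose and fell numbered 36 and 0 for matrix genes, 1 (Cox8a) and 77 for respiratory subunits, 17 and 0 for macrophage markers, 13 and 1 for fibroblast markers, and 2 and 29 for fatty acid oxidation. They numbered 6 and 18 for sarcomere genes, 3 and 12 for mitochondrial regulators, 5 and 1 for erythrocyte and platelet markers, 4 and 2 for neutrophil markers, and 2 and 7 for smooth muscle and pericyte markers. The counts adjusted over the list alone were the same as over all features for 18 of the 32 lists.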

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

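The tests in this part were chosen after the result was seen. The control spots, which the comparisons do not use, held a difference between groups: the 75th percentile of each array less its E1A spike-in probes, RNA added in a set amount, was higher in Tead1 icKO by 0.46 (log2). It was -0.54 ± 0.21 (SD, n = 3) in controls and -0.08 ± 0.05 in icKO, with every icKO array above every control (exact two-sided permutation p = 0.1, the smallest the design can give). Brighter labelling or scanning of the whole array would raise the spike-ins as far as the 75th percentile, which rose by 0.58, and they differed by 0.12. That argues against it only if the spike-ins were added evenly, and the 75th percentile less the spike-ins varied by 0.41 within controls, so uneven spike-in amounts and brighter labelling cannot be told apart from a larger labelled share of RNA in icKO. The last would be a biological difference of the groups, and was not tested. On slide row 1 the 75th percentile less the spike-ins was -0.73 and -0.56 in controls and -0.14 in icKO. On row 2 it was -0.32 in controls and -0.05 and -0.04 in icKO. Slide columns were 1, 1 and 2 in controls and 2, 3 and 3 in icKO. Position on the slide was not tested for this difference. Slide column largely follows the groups, so its effect cannot be told apart from the group either. Both rows held both groups, and within each row every icKO array lay above every control.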

How the results depend on the processing

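Of 2700 values of named genes under the alternatives, 2578 kept their side of the threshold, 109 lost the call, 10 gained it and 3 turned sign. Of 706 values of gene lists, 654 kept their side of the threshold, 20 lost the call and 32 gained it. For genes and lists, a turn of sign was counted only where the main fit or the alternative passed the threshold. Values that passed in neither may have turned sign without being counted. The cause was not tested for any change below unless stated. With median scaling 3657 features were lower. With no filter on dim probes 6123 differed (2127 higher, 3996 lower) among more features tested, 5 lists were lower and the first component held 41.4%. With spike-in scaling, added after seeing the data, 7491 were higher and 1591 lower, since it adds 1 shift to every feature. Of the named genes called in the main fit, Tead1 (0.064), Casq2 (0.043) and Shmt2 (0.11) turned sign with it. With a fold change of at least 1.5, 4200 were lower. With an estimated correlation 0 lists were higher and 0 lower, and fry called 11 lower. Without 1 array at a time, 7548 to 9033 features differed, each fit having fewer arrays. The Tead1 difference was -0.24 (adjusted p = 0.186) with median scaling, -0.40 (adjusted p = 0.122) with no filter, -0.38 (adjusted p = 0.0631) with slide row as a block, and -0.47 to -0.35 without 1 array. Its adjusted p ranged from 0.0109 to 0.753 over all alternatives. With the replicate number as a block, 2797 features were higher and 5084 lower, and Tead1 stayed at -0.40 (adjusted p = 0.0509). The labels give both groups numbers 1 to 3, but arrays with the same number correlated at -0.05, -0.13 and 0.00 in their deviations. Each array correlated best with an array of another number. The values thus give no sign that the numbers pair the samples, though they cannot exclude a pairing. The slide block was not run, since all arrays share 1 slide. Slide column, 1 or 2 in controls and 2 or 3 in icKO, was not used as a block and largely follows the groups. Signal over background limits the dim genes, which have only bounds.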

Other observations

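In this part the tests on sarcomere genes, on Esr1 and on MCAT elements were chosen after the results were seen. So were spike-in scaling, slide row as a block and the median spot signal used for normexp, wherever they appear. The others were chosen before. Several stress and metabolic lists held genes moving both ways. Of 24 antioxidant genes, 6 rose and 10 fell (camera adjusted p = 0.763), against 11 and 3 with spike-in scaling. Gpx3, an extracellular glutathione peroxidase, rose by 3.83 ± 0.15 (SE, n = 3 and 3), and the mitochondrial Sod2 and Prdx5 fell by 1.23 ± 0.09 and 1.05 ± 0.09. Of 23 glycolysis genes, 5 rose and 9 fell (camera adjusted p = 0.839), against 9 and 5 with spike-in scaling. The glucose transporter Slc2a1 rose by 1.44 ± 0.17 and the platelet isoform Pfkp by 1.37 ± 0.09, while the muscle enolase Eno3 fell by 2.04 ± 0.15 and Ldhb by 1.40 ± 0.09. Of 16 heat shock genes, 1 rose and 9 fell, against 5 and 4 with spike-in scaling (camera adjusted p = 0.2). The mitochondrial chaperonins Hspd1 and Hspe1 fell by 1.65 ± 0.08 and 1.17 ± 0.12, and Hspb7 rose by 1.11 ± 0.13.

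Of 26 genes of the unfolded protein and integrated stress responses, 9 rose and 4 fell, against 11 and 0 with spike-in scaling (camera adjusted p = 0.105), and the list was called higher without control replicate 1 (adjusted p = 0.0363), with normexp (adjusted p = 0.0173), no filter on dim probes (adjusted p = 0.018) and slide row as a block (adjusted p = 0.0333). The transcription factor Atf3 rose by 2.09 ± 0.27 (SE) and the kinase-like Trib3 by 1.26 ± 0.16, while the chaperone Hspa5 fell by 0.64 ± 0.11, a call lost with spike-in scaling (-0.18, adjusted p = 0.35). Of 21 p53 and DNA damage targets, 8 rose and 4 fell, against 11 and 0 with spike-in scaling (camera adjusted p = 0.0899), and the list was called higher with normexp (adjusted p = 0.0316), no filter on dim probes (adjusted p = 0.0169) and fry (adjusted p = 0.00562). It held the cell cycle inhibitor Cdkn1a at 2.46 ± 0.23, where a dimmer probe gave -0.17. Of 22 proliferation genes, 1 rose (Cenpa, 0.96 ± 0.18) and 5 fell, including Ccne1 by 1.26 ± 0.21, and 6 and 2 did so with spike-in scaling (camera adjusted p = 0.775). That list stood at 0.23 on icKO replicate 2 and at -0.18 and -0.24 on the other icKO arrays, against -0.04 to 0.16 in controls. Of 22 cardiac transcription factors, 2 rose and 5 fell, or 7 and 2 with spike-in scaling (camera adjusted p = 0.763), with Hopx at -2.28 ± 0.17. Of 23 interferon-stimulated genes 2 rose, or 8 with spike-in scaling (camera adjusted p = 0.105), with Irf7 at 1.11 ± 0.20. The list stood at 0.56 on icKO replicate 2 and at -0.13 and -0.03 on the other icKO arrays, and its excess of 0.26 became 0.03 without replicate 2 (adjusted p = 0.747). It was called higher without control replicate 3 (adjusted p = 0.0225), icKO replicate 1 (adjusted p = 0.0248) or icKO replicate 3 (adjusted p = 0.0447), and with no filter on dim probes (adjusted p = 0.0169) and slide row as a block (adjusted p = 0.00135). In the neural list Ncam1 rose by 4.07 ± 0.28, with 2 of 3 control arrays above background, and by 2.26 with a probe above background on all 6 arrays, and Uchl1 by 2.39 ± 0.12. Th, which makes catecholamines, fell by 0.99 ± 0.09.

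The respiratory chain genes fell together, with a median log2 difference of -0.85. Among 10000 random lists of the same size matched on mean signal the middle 95% of medians ran from -0.46 to -0.23, around -0.35. By these lists, compression of bright probes may account for part of the fall but not all of it. Their genes were drawn independently, while respiratory chain genes had an estimated inter-gene correlation of 0.437. The range may therefore be too narrow for such a list. A lower share of cardiomyocyte RNA as the whole cause would move sarcomere genes as far, and these lay 0.54 above the respiratory chain genes, with a pooled SD between arrays of 0.06, and 0.49 above with quantile normalization. It would also raise markers of all other cell types alike, but only if those types kept their proportions to each other, which is not known here. Macrophage markers lay 1.49 and smooth muscle and pericyte markers -0.22 from all genes. The smooth muscle and pericyte list shares Des with the sarcomere list and Abcc9 with the ion channel list. Its arrays also overlapped between groups, so the cell type markers do not decide the question. Loss of Tead1 or the presence of Cre stays open as an untested hypothesis.

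Esr1 gave 8.59 through 1 probe, at 1.90, 5.12 and 4.66 on the icKO arrays and -5.69, -2.87 and -5.54 on the controls. A candidate explanation is the Myh6-CreER transgene, whose transcript carries part of an estrogen receptor coding sequence: the 2 other Esr1 probes differed by 0.18 and 0.10. Induction of the endogenous gene cannot be told apart from it, since those probes were above background on at most 1 array and may not detect the transcript. The probe positions are not known here, and the source of the signal on control replicate 2 was not tested.

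Acta1 and Nppb have promoters with MCAT elements, which bind TEAD factors, so a hypothesis was that genes with such elements fell as a set. A list of 8 (Acta1, Nppb, Tnnt2, Myh7, Myh6, Acta2, Adra1a and Myocd), written from general knowledge after several of their values were seen, gave a camera p of 0.0368, unadjusted and not 1 of the 32 lists, and 0.174 with an estimated correlation. That list holds the 2 genes that prompted it. Without them, a change made after the first p was seen, 3 of 6 genes fell, none rose, and the camera p was 0.123. With spike-in scaling 1 fell, 1 rose and the p was 0.0444, and the 18 other settings gave 1 to 4 falls, 0 or 1 rise and a p of 0.0541 to 0.68. The test did not reliably separate these genes from others and the hypothesis stays open.

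Of the 10 splits of the 6 arrays into 3 and 3, the real one called 9974 features (limma) and the highest of the others called 0, with 173 to 474 features at an unadjusted p under 0.05. That is 1 of 10 splits with as many. For gene lists the real split called 13 and the highest of the others 15, and 5 of the 10 splits called as many as the real one. With 10 splits the share is never under 0.1, which is too few for a share under the threshold. The other splits also mix arrays of both groups and keep part of the group difference. Their counts of features and lists therefore do not show what chance alone gives.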
